A study of Mus musculus with 12 samples.

How the data were processed

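The series holds 12 mammary tumours of FVBN mice, dissociated and loaded on a ddSEQ instrument, with libraries made by the SureCell WTA 3′ protocol. The deposited tables hold raw UMI counts per gene and cell, 1 table per tumour, each with 24421 genes. Per the labels, several libraries of a tumour were joined into 1 table. The submitters' processing notes name Seurat 3.0.2 and the genome build GRCm38, and the aligner, the gene counting, the annotation and the calling of cells were not given in the sources used here. Whether tumours came from separate animals is not stated, so p values measure the spread between samples. The tables come in 2 layouts: 4 tumours (p95 and d16 tumours 1 and 2) keep gene names intact, and in the 8 others, names of the March and Sept families had become dates, of which 27 were mapped back by position in the table. Altogether 1708 gene names were restored to their usual form and 23369 names were found in GENCODE release M21, which gave positions and gene types. The tables list 0 mitochondrial genes, so no filter on mitochondrial share was possible.

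Cells with at least 200 detected genes were kept, 7366 of 8486 barcodes. Counts were scaled to 10000 UMIs per cell and log transformed with scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9). The 2000 most variable genes gave 30 principal components, a graph of 15 nearest neighbours and 21 Leiden clusters at resolution 1, without integration of tumours. A cluster took the name of the marker set with the highest mean standardised level if at least 3 of its markers were detected in 10% of its cells and its 10 leading genes did not hold more markers of another class. It also stayed unnamed with a score of 0 or less, or with few UMIs for its tumour and no own marker among those genes. The exact form of these last conditions was set after the data were examined. Luminal and basal names together form the epithelial-like class. Simulated doublets scored each tumour with 30 neighbours, at most 5% of a tumour's cells were called, and the 288 predicted doublets (3.91% of cells) stayed in the reported results. Free RNA was not removed, so UMIs of 1 cell type in another are not proof of expression. No table repeated another (lowest chi-square per degree of freedom 3.56 between 2 tumours, at most 3 shared barcodes).

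UMI counts were summed per tumour over all kept cells (whole tumour) or over the cells of a class, and tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) after filterByExpr and TMM normalisation, with a Benjamini-Hochberg adjusted p threshold of 0.05. Log2 fold changes carry an SE taken from the unshrunk fold and the F statistic, and levels are TMM-normalised CPM (UMIs per 1e6 UMIs) as mean ± SD. The comparisons were d16 (3) against p95 (5) among nulliparous tumours, multiparous (4) against nulliparous (8), and solid nodular (3) against metaplastic (7), with the 2 mixed tumours left out of the last. The multiparous tumours were left out of the first because their form of HER2 is not labelled. Other classes were tested where each group kept 3 tumours with at least 20 cells. Shares of cells were compared by a two-sided exact permutation test over tumours (scipy 1.17.1), adjusted over the 8 named classes. Of 35 gene lists, those with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated one, and with fry. Groups, comparisons, tests, gene lists, marker sets, the settings for cells and the rule for named genes were fixed before the data were examined.

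The rule names, per fit, up to 10 genes rising and 10 falling the most among those with an adjusted p under 0.05 and an average log2 CPM of at least 4, or, where fewer than 5 pass, all of these and the 5 genes with the smallest p. It adds up to 4 members of each described list and a panel of 18 genes. That 5 lists per fit, those with the smallest camera p, are described, with up to 3 members each, was decided after the results were seen. A further list member is not reported here. Alternatives were DESeq2 1.42.0, limma voom with and without the title number as a block, RLE size factors, no low-count filter, 500 detected genes per cell, removal of doublets, Leiden resolution 2 (36 clusters), covariates, subsets of tumours and leaving out each tumour. A gene with 0 UMIs in a group is given as a bound against 3 counts over the group, and intervals are exact 95% intervals that cover counting error only.

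The fits were tested on simulated counts with 200 changed genes. At a true log2 fold change of 1, 2 and 3, they recovered 2.98, 67.2 and 95.5% of changed genes in whole tumours for genotype, 22.4, 86.6 and 93.9% for parity and 7.46, 79.1 and 93.9% for phenotype. In epithelial-like cells the values were 1.51, 49.2 and 92.4%, 1.49, 71.6 and 95.5%, and 1.49, 56.7 and 92.4%. False calls were 2 of 112 for genotype in whole tumours and 10 of 105 in epithelial-like cells, 6 of 141 and 5 of 117 for parity and 7 of 127 and 6 of 106 for phenotype. For genotype, regrouped real tumours gave up to 912. Trajectories, cell cycle phase, copy number and ligand-receptor pairs were not analysed.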

Results

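Single-cell 3′ RNA-seq counts described 12 mammary tumours of mice carrying the HER2 Crainbow transgene, a multicolour construct in which Cre recombinase switches on a labelled form of HER2, the receptor tyrosine kinase encoded by ERBB2. Nulliparous animals gave 8 tumours, of which 3 were labelled d16 and 5 p95 for the form of HER2. Multiparous animals gave 4 tumours whose form of HER2 was labelled unknown. By histology, 3 tumours were solid nodular (d16 tumour 1 and multiparous tumours 2 and 4), 7 were metaplastic or invasive (called metaplastic here) and 2 were mixed (multiparous tumours 1 and 3). The animals were 15 to 21 weeks old. Total UMI counts were 140348, 1074991, 2116421, 2425070 and 2285830 in p95 tumours 1 to 5, and 297340, 1972987 and 4394398 in d16 tumours 1 to 3. The multiparous tumours 1 to 4 held 3044255, 4041724, 2159993 and 948488 UMIs. Of 8486 barcodes, 7366 had the required number of detected genes, with a median UMI count per kept cell of 449 (d16 tumour 1) to 4536 (multiparous tumour 2).

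Epithelial-like cells, named from keratin and junction markers such as Epcam, Krt8, Krt5 and Krt14, made up 3584 of the kept cells (48.7%). Macrophage-like cells numbered 1047, T or NK-like cells 442, fibroblast-like cells 314 and neutrophil-like cells 307. Smaller classes were dendritic-like (158 cells), pericyte-like (152) and endothelial-like cells (112, of which 26.8% were predicted doublets). Another 1250 cells in clusters 2, 9 and 15 took no name, since their leading genes held more markers of another class than of the class they matched best. Those genes included Mmp13 and Mmp10 in cluster 2, Thbs4 in cluster 9 and Slc6a15 and Krt23 in cluster 15. Cluster 15 came almost wholly from multiparous tumour 4, where it held 228 of 344 cells, and that tumour kept 15 epithelial-like cells (4.36%, exact 95% interval 2.46 to 7.09%). The epithelial-like class was not of 1 kind: cluster 0, led by the ribosomal RNA gene Rn45s, held 249 of the 313 epithelial-like cells of d16 tumour 1, 338 of 726 in d16 tumour 2 and 61 of 118 in p95 tumour 1. Cluster 3, led by the keratin genes Krt5 and Krt16, held 160 of 312 in p95 tumour 3, and cluster 7, led by the Wnt ligand gene Wnt5b, held 85 of 176 in p95 tumour 4. Multiparous tumour 2 was spread over clusters 4 (250 of 496 cells), led by Gpx2, and 6 (197 cells), led by the casein genes Csn1s2a and Csn2.

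**Figure D1:**
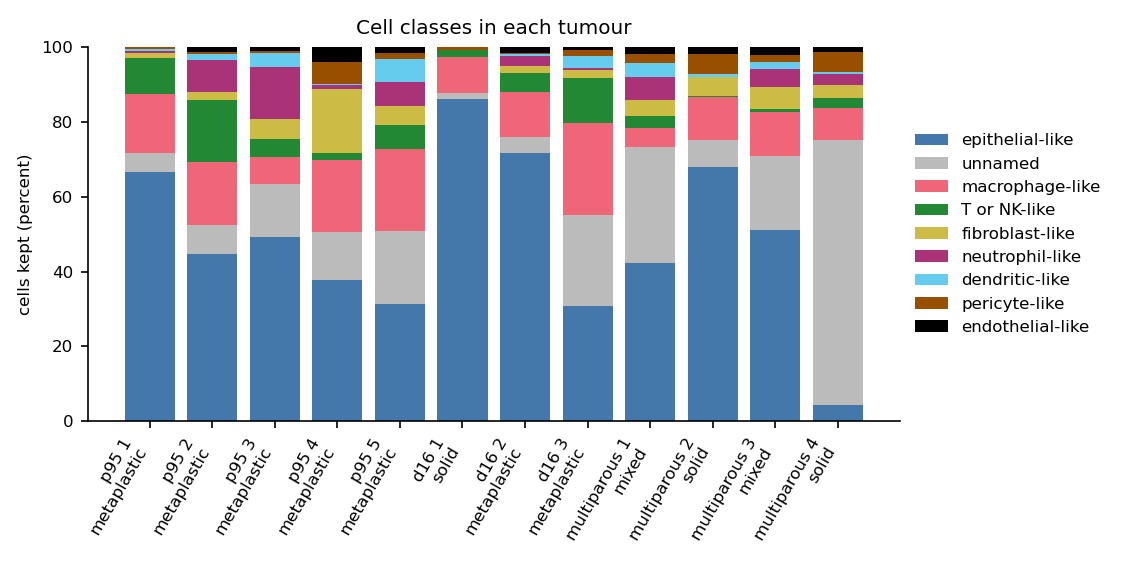
Share of kept cells (percent, bars stacked to the whole) in each cell class for each of the 12 tumours, grouped by form of HER2 and parity. Multiparous tumour 4 stands apart, with 15 epithelial-like cells and most cells in an unnamed cluster.

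The comparison of d16 with p95 tumours asks how tumours driven by different forms of HER2 differ when both arose in nulliparous animals. All p95 tumours are metaplastic and d16 tumour 1 is solid nodular, so form of HER2 and growth pattern are partly mixed in this comparison. In whole tumours Mtmr14, a phosphoinositide phosphatase gene on chromosome 6 from 113237843 to 113281392 (GRCm38), stood at 142 ± 63.6 against 36.5 ± 9.19 CPM (mean ± SD, n = 3 d16 and 5 p95 tumours), a log2 fold change of 2.00 ± 0.32 (SE). Gpx2, which encodes a glutathione peroxidase of epithelia, stood at 233 ± 195 against 7.25 ± 6.65 CPM, and the milk casein gene Csn3 at 9093 ± 6145 against 6086 ± 4925 CPM. Keratin genes of basal and squamous epithelium lay the other way, with Krt5 at 74.2 ± 106 against 1043 ± 1774 CPM and Krt14 at 168 ± 219 against 2012 ± 3144 CPM. None of these genes passed the test, with edgeR adjusted p values of 0.904 for Mtmr14 and 0.932 for Gpx2. Mfsd7c, a transporter gene, had a log2 fold change of 3.90 ± 0.87, Gjb1 of 3.66 ± 0.83 and Pglyrp1 of 3.26 ± 0.75. Krtdap, a gene of differentiating keratinocytes, had 0 UMIs in d16 and 737 in p95 tumours, so its level was at least 202-fold lower in d16 tumours against a floor of 3 counts over the group, and 21.5-fold without p95 tumour 3, which held most of those UMIs.

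Gene lists are given with the median log2 fold change of their tested genes and the adjusted p of camera at a preset correlation of 0.01 and with the correlation estimated. By gene group, all 12 measured squamous and keratinising genes lay lower in d16 whole tumours (median -2.84, camera adjusted p = 3.51e-05 preset and 0.564 estimated), with log2 fold changes of -6.01 ± 2.31 for Krt6b and -4.03 ± 1.57 for Krt16. So did 24 of 24 genes of the epithelial-mesenchymal transition (median -0.91, camera adjusted p = 8.23e-09 preset and 0.564 estimated), among them the calcium-binding S100a4 (-1.78 ± 0.68) and Tgfbi (-0.87 ± 0.42). Of the chemokines and cytokines, 24 of 29 lay lower (median -0.81, camera adjusted p = 2.51e-06 preset and 0.564 estimated), such as Cxcl5 (-2.11 ± 0.79), Cxcl12 (-1.79 ± 0.73) and Ccl9 (-1.53 ± 0.63). Fibroblast markers lay lower in 12 of 12 cases (median -0.99, camera adjusted p = 2.37e-05 preset and 0.564 estimated). Clec3b lay at -2.10 ± 0.86, Dpt at -2.39 ± 1.06 and Gsn at -1.02 ± 0.62, while fibroblast-like cells made up 1.36 ± 1.18% against 6.13 ± 6.40% of cells. The unnamed clusters 2 and 9, with the matrix genes Col6a3 and Fmod among their leading genes, lay outside that class. They made up 5.95 ± 8.70% against 7.73 ± 4.03% (cluster 2) and 3.96 ± 4.12% against 4.00 ± 3.08% of cells (cluster 9). Neutrophil markers lay lower in 8 of 8 cases (median -1.43, camera adjusted p = 3.97e-05 preset and 0.564 estimated). Clec4d lay at -1.99 ± 0.52, Il1r2 at -1.31 ± 0.66 and the gelatinase gene Mmp9 at -2.36 ± 1.34, while neutrophil-like cells made up 1.01 ± 1.36% against 6.12 ± 5.66%. No member of these 5 lists passed over all genes tested, and 1 neutrophil gene passed when adjusted over the list alone. Without p95 tumour 3 the squamous median was -1.26. Without d16 tumour 1 the medians of transition, cytokine and fibroblast genes were -0.50, -0.42 and -0.46, and without d16 tumour 3 those of squamous, transition and fibroblast genes -4.64, -2.26 and -2.003. Interferon response genes lay higher in d16 tumours (median 0.54, camera adjusted p = 0.00152 preset and 0.564 estimated), with a median of 0.27 without p95 tumour 5. The G2M genes of cell division lay higher as well (median 0.48, camera adjusted p = 2.53e-04 preset and 0.564 estimated), but their median was -0.070 without d16 tumour 1.

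In epithelial-like cells Mtmr14 again led the ranking, at 189.5 ± 54.3 against 39.9 ± 17.3 CPM (log2 fold change 2.40 ± 0.34, adjusted p = 0.161 in edgeR, n = 3 and 5), with every d16 tumour above every p95 tumour. Its neighbour Brpf1, a histone acetyltransferase subunit gene, followed at 292 ± 189 against 71.5 ± 21.9 CPM (log2 fold change 2.10 ± 0.45), both beside Gt(ROSA)26Sor, a locus often used to insert transgenes. The gap junction gene Gjb1 stood at 39.0 ± 26.9 against 6.16 ± 4.50 CPM. The innate immunity gene Pglyrp1 stood at 135 ± 101 against 24.7 ± 25.7 CPM. Genes of the epithelial-mesenchymal transition lay lower in 19 of 19 cases (median -1.63, camera adjusted p = 1.27e-09 preset and 0.5257 estimated). The integrin gene Itga5 lay at -2.53 ± 0.80, Tgfbi at -2.35 ± 0.78 and S100a4 at -2.71 ± 0.95. Fibroblast markers lay about as low in the same cells, in 7 of 8 cases (median -1.53, camera adjusted p = 0.00407 preset and 0.5257 estimated), with a median of -0.77 without p95 tumour 5, and free RNA was not removed. Squamous genes lay lower in 12 of 12 cases (median -2.69, camera adjusted p = 2.07e-05 preset and 0.5257 estimated). Krt6b lay at -5.75 ± 2.13 and the cornified envelope gene Sbsn at -2.31 ± 0.90. Krtdap had 0 UMIs in d16 and 733 in p95 epithelial-like cells, at least 213-fold lower with and 24.5-fold lower without p95 tumour 3, and without it the median of the squamous genes was -1.28. Basal-myoepithelial genes lay lower in 15 of 16 cases (median -1.53, camera adjusted p = 2.94e-04 preset and 0.5257 estimated). Igfbp2 lay at -1.74 ± 0.73, the laminin gene Lamb3 at -2.02 ± 0.96 and Krt14 at -3.27 ± 1.71. Collagen and matrix genes lay lower in 16 of 22 cases (median -1.09, camera adjusted p = 2.57e-04 preset and 0.5257 estimated), among them Col6a1 (-2.26 ± 0.70), Col5a1 (-2.18 ± 0.74) and Col6a2 (-1.82 ± 0.76). Chemokine and cytokine genes did so in 18 of 23 cases (median -0.93, camera adjusted p = 4.30e-05 preset and 0.144 estimated). Cxcl3 lay at -2.29 ± 0.75, Tnf at -0.93 ± 0.32 and Ccl2 at -1.49 ± 0.60. No member of these 6 lists passed over all genes or adjusted over the list alone. Without d16 tumour 3 the medians of transition, squamous, basal and matrix genes were -3.49, -5.05, -2.88 and -2.70, and that of matrix genes was -0.67 without d16 tumour 2. Among receptor genes of the ERBB family, mouse Erbb2 stood at 71.5 ± 30.6 against 92.0 ± 45.7 CPM and Egfr at 43.9 ± 4.35 against 52.2 ± 24.6 CPM, and Erbb4 was at or under the floor of 3 UMIs in both groups. No row of the tables names human ERBB2 or a reporter, so the transgene itself could not be measured.

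The edgeR test of d16 against p95 passed 0 of 11061 genes in whole tumours and 0 of 9255 genes in epithelial-like cells, beside 483 and 514 genes at an unadjusted p under 0.05. DESeq2 passed 3 and 2 genes, limma voom without a block 0 and 0, and limma voom with the title number as a block 0 and 1. Groups did not overlap for 1.93% of genes in whole tumours and 2.51% in epithelial-like cells, where chance gives 3.57%. Epithelial-like cells made up 62.9 ± 28.7% against 46.0 ± 13.5% of kept cells (difference 16.9 points, two-sided exact permutation p = 0.304, smallest p allowed 0.0179, adjusted p over 8 classes = 0.771), a difference smaller than the SD of the d16 tumours. Its sign turned in the date-like layout of gene names, where only d16 tumour 3 stands against 3 p95 tumours (-8.62 points), and it reached 33.0 points without d16 tumour 3 (exact p = 0.0476). Without d16 tumour 3, 2 genes passed in whole tumours. With layout as a covariate no gene passed in either fit (314 and 354 at an unadjusted p under 0.05 in edgeR), and the fold change of Mtmr14 in epithelial-like cells was 2.01 within the intact layout and 2.52 within the date-like layout.

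**Figure D2:**
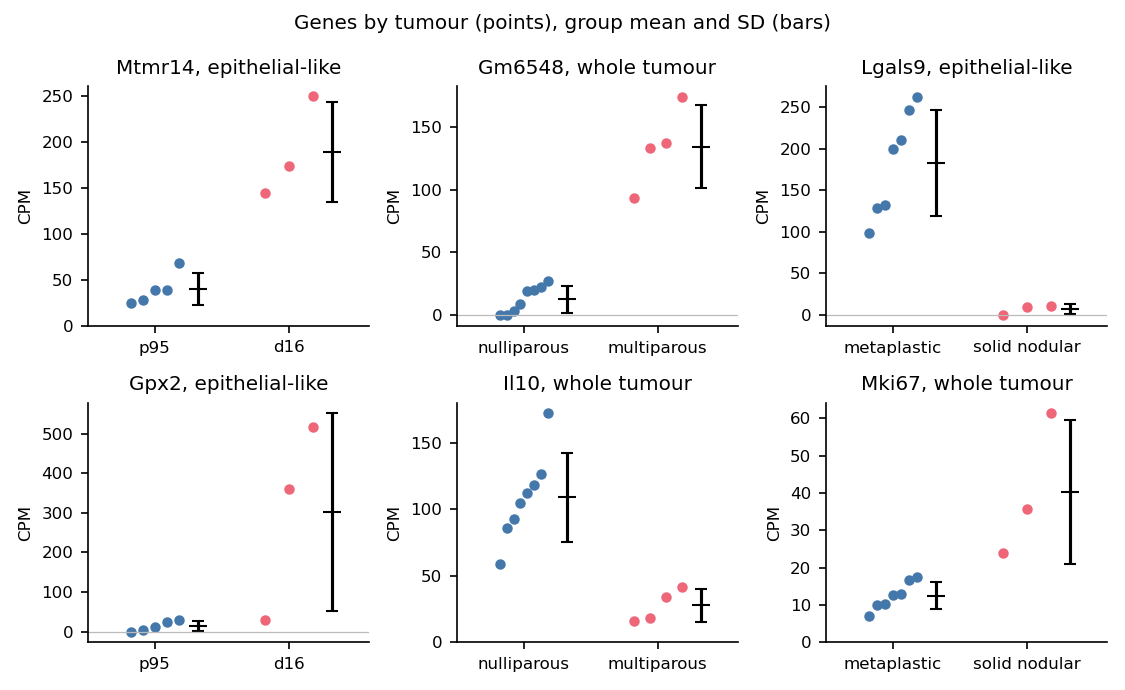
Normalised CPM (TMM) per tumour (points) with the mean and SD of each group (bars) for Mtmr14 and Gpx2 in epithelial-like cells, Gm6548 and Il10 in whole tumours, Lgals9 in epithelial-like cells and Mki67 in whole tumours. Gm6548, Il10 and Lgals9 passed the test of their comparison, and the 3 solid nodular tumours lie below all 7 metaplastic tumours for Lgals9. Of these 3, multiparous tumour 4 rests on 15 cells, where 3 counts would be 204 CPM without TMM factors.

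The parity comparison asks whether past pregnancy goes with another tumour state. Parity cannot be told apart from the form of HER2, unknown in every multiparous tumour, or well from growth pattern, as none is metaplastic. In whole tumours the immune genes Il21r, Il10 and Il10ra fell (n = 4 multiparous and 8 nulliparous). Their log2 fold changes were -3.05 ± 0.50, -1.94 ± 0.32 and -1.55 ± 0.26 (SE), at 5.13 ± 2.86 against 43.7 ± 22.3, 27.8 ± 12.3 against 109 ± 33.3 and 10.1 ± 2.14 against 29.6 ± 7.33 CPM. With T or NK-like and macrophage-like shares lower, no fall within cells was shown. Gene models without a known function rose: Gm12657 by 3.23 ± 0.40, Gm6548 by 3.11 ± 0.46 and Rps19-ps3 by 2.40 ± 0.40 on the log2 scale. Those 3 are processed pseudogenes in the annotation, so their counts are uncertain where reads also match the parent gene. Adjusted p was 0.00992 for Gm12657, 0.0285 for Gm6548 and 0.0420 for each of the other 4 in edgeR. Rps19-ps3, Il21r, Il10 and Il10ra no longer passed with file layout as a covariate, at log2 fold changes of 2.29 ± 0.48, -2.79 ± 0.51, -2.08 ± 0.34 and -1.36 ± 0.26 (adjusted p = 0.203, 0.139, 0.0747 and 0.173). None of these 4 passed within the date-like layout (adjusted p = 0.219 for Rps19-ps3, 0.147 for the others), without the 2 shallowest tumours (0.0792, 0.0563, 0.0636 and 0.0636) or under limma voom with the block (0.0901 for each). Rps19-ps3 and Il10ra also fell short without predicted doublets (0.0601 and 0.0951), while Gm12657 and Gm6548 passed in all 5 of these settings. On GRCm38 Il10 lies on chromosome 1 from 131019845 to 131024974, Il21r on chromosome 7 from 125603429 to 125633570, Il10ra on chromosome 9 from 45253837 to 45269149 and Gm12657 on chromosome 4 from 94599385 to 94599795. Below the level that the naming rule asks for, and named after their values were seen, Gm10548, 1700073E17Rik and Rnps1 also rose, by 3.30 ± 0.43, 4.48 ± 0.61 and 2.56 ± 0.41 on the log2 scale.

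Antigen presentation and immune markers lay lower in multiparous whole tumours. All 10 MHC class II genes did (median -1.75, camera adjusted p = 2.96e-19 preset and 0.0954 estimated), and 9 passed when adjusted over the list alone but 0 over all genes, with Cd74, the invariant chain, at 181 ± 59.2 against 1072 ± 578 CPM (log2 fold change -2.56 ± 0.52, adjusted p = 0.111), Cd83 at -1.84 and H2-DMb1 at -1.61. Interferon response genes lay lower in 27 of 28 cases (median -1.44, camera adjusted p = 6.52e-17 preset and 0.223 estimated), of which 6 passed over the list alone, among them Cxcl10 (-2.40 ± 0.52), Isg15 (-2.04 ± 0.55) and Irf7 (-1.81 ± 0.50). T or NK markers lay lower in 8 of 8 cases (median -2.49, camera adjusted p = 8.88e-10 preset and 0.223 estimated). The CD3 chain gene Cd3d lay at -4.57 ± 1.08, Cd3e at -3.20 ± 0.82 and Cd3g at -3.59 ± 1.02, and 7 passed over the list alone. Beside them, T or NK-like cells made up 1.74 ± 1.40% against 7.32 ± 5.13% of cells (exact permutation p = 0.0545, adjusted p = 0.178). Macrophage markers lay lower in 12 of 12 cases (median -1.18, camera adjusted p = 6.12e-11 preset and 0.223 estimated). Tyrobp lay at -1.38 ± 0.34, the protease gene Ctss at -1.96 ± 0.50 and the complement gene C1qa at -1.78 ± 0.46, and 7 passed over the list alone. Macrophage-like cells made up 9.17 ± 3.08% against 15.9 ± 6.02% (exact permutation p = 0.0667, adjusted p = 0.178). MHC class I genes lay lower in 17 of 18 cases (median -0.61, camera adjusted p = 1.15e-08 preset and 0.294 estimated). The immunoproteasome gene Psmb9 lay at -1.48 ± 0.36 and Psmb8 at -1.16 ± 0.34, B2m at -0.98 ± 0.31, and 3 passed over the list alone. Over all genes 0 members of these lists passed. For the milk and alveolar genes the signs differed, since the camera test put them lower (median 0.014, camera adjusted p = 0.0220 preset and 0.735 estimated) with a mean of -0.061, and the median was -2.08 without multiparous tumour 2. Collagen and matrix genes lay higher (median 0.27, camera adjusted p = 0.00390 preset and 0.735 estimated) but lower with file layout as a covariate or without multiparous tumour 1 (median -0.11 for the latter).

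In epithelial-like cells no gene passed, and the interferon genes again lay lower in multiparous tumours, in 26 of 26 cases (median -1.60, camera adjusted p = 7.85e-13 preset and 0.429 estimated). Ifi27l2a stood at 3.63 ± 3.91 against 95.3 ± 131 CPM, Rsad2 at 1.47 ± 1.02 against 23.2 ± 22.8 CPM and Oasl2 at 5.92 ± 5.28 against 25.9 ± 15.6 CPM, and 1 gene of the list passed when adjusted over the list alone. In multiparous tumour 4 (15 cells) 3 counts would be 204 CPM without TMM factors. It thus shows no lower level of these 3 genes, Cd74 or Pgr. MHC class II genes lay lower in 6 of 6 cases (median -2.06, camera adjusted p = 7.65e-09 preset and 0.198 estimated), 5 of them over the list alone, with Cd74 at 5.84 ± 6.05 against 54.0 ± 54.2 CPM, H2-Aa at -2.38 ± 0.70 and Ctss at -3.03 ± 1.01. Cd74, a gene of antigen-presenting cells, stood lower in epithelial-like cells than in whole tumours. Macrophage markers lay lower in the same epithelial-like cells, in 7 of 7 cases (median -1.07, camera adjusted p = 0.00416 preset and 0.429 estimated), with a median of -0.39 without p95 tumour 2 and a camera adjusted p of 0.623 with file layout as a covariate. MHC class I genes lay lower in 17 of 18 cases (median -0.68, camera adjusted p = 1.70e-06 preset and 0.429 estimated), such as B2m (-1.12 ± 0.40), H2-Q4 (-1.60 ± 0.60) and Psmb9 (-1.27 ± 0.52). Respiratory chain genes lay lower in 30 of 33 cases (median -0.32, camera adjusted p = 1.05e-06 preset and 0.429 estimated). Ndufa1 lay at -1.09 ± 0.37, Ndufs6 at -0.60 ± 0.28 and Cox6c at -0.60 ± 0.28, and the median was -0.20 without multiparous tumour 4 and -0.63 without multiparous tumour 2. Luminal keratin and junction genes did so in 22 of 25 cases (median -0.45, camera adjusted p = 3.09e-04 preset and 0.429 estimated). Cldn7 lay at -1.60 ± 0.51, Cldn4 at -1.14 ± 0.49 and Krt19 at -2.21 ± 0.90. No member of the last 3 lists passed over all genes or adjusted over the list alone. The smallest p values belonged to Gm6548 (2.69 ± 0.47, adjusted p = 0.197 in edgeR), 1600029O15Rik (2.81 ± 0.50), Rasd1 (-2.36 ± 0.46), Gm12657 (3.03 ± 0.61) and Rps19-ps3 (2.03 ± 0.41). The progesterone receptor gene Pgr stood at 1.70 ± 1.72 against 9.93 ± 11.2 CPM and Erbb2 at 66.1 ± 16.6 against 88.0 ± 41.2 CPM.

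The edgeR test passed 9 of 11242 genes in multiparous against nulliparous whole tumours, 6 higher and 3 lower, and 0 of 9520 genes in epithelial-like cells (330 at an unadjusted p under 0.05, 5 by DESeq2, 0 by limma voom without and 0 with the block). DESeq2 passed 157 genes in whole tumours, the 9 among them, and limma voom 15 without and 3 with the block. Groups did not overlap for 1.16% of genes in whole tumours and 0.504% in epithelial-like cells, where chance gives 0.404%. Epithelial-like cells made up 41.5 ± 26.9% against 52.3 ± 20.4% of kept cells (difference -10.8 points, two-sided exact permutation p = 0.457, smallest p allowed 0.00202, adjusted p = 0.860). Pericyte-like cells made up 3.81 ± 1.82% against 1.43 ± 1.84% (exact permutation p = 0.0404, adjusted p = 0.178). Cluster 15, from multiparous tumour 4, lay outside the named classes and took a mean of 16.6% of multiparous against 0.0519% of nulliparous cells, cluster 2 9.60% against 7.06%. The count in whole tumours was 0 with phenotype as a covariate (1199 at an unadjusted p under 0.05), 4 with file layout as a covariate, 4 within the date-like layout and 20 without d16 tumour 1. It was 5 without p95 tumour 2 and 3 without any 1 of p95 tumours 1 and 5, d16 tumours 2 and 3 or multiparous tumours 1, 3 and 4, and the intact layout holds no multiparous tumour. With phenotype in the fit the contrast rests on d16 tumour 1 against multiparous tumours 2 and 4, the only solid nodular tumours. In epithelial-like cells 1 gene passed without p95 tumour 3.

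The comparison of solid nodular with metaplastic tumours asks which genes and cells go with growth pattern. In epithelial-like cells Lgals9, which encodes the immunoregulatory lectin galectin-9, fell to 6.93 ± 6.03 from 183 ± 63.4 CPM (n = 3 solid nodular and 7 metaplastic tumours), a log2 fold change of -4.15 ± 0.53 (edgeR adjusted p = 0.00995). Each of the 3 lay lower than all 7, but multiparous tumour 4 gave only 15 cells, where 3 counts would be 204 CPM without TMM factors. That is above the metaplastic mean of 167 CPM on the same scale, so the value of multiparous tumour 4 does not show a lower level. The gene did not pass with the title number as a block in limma voom (adjusted p = 0.0745), with parity as a covariate (-4.22 ± 0.91, 0.254), within the intact layout (0.218), without the 2 shallowest tumours (-4.19 ± 0.66, 0.398) or without d16 tumour 1 (0.279), multiparous tumour 2 (0.242) or multiparous tumour 4 (0.0502). It lies on chromosome 11 from 78962974 to 78984946 of GRCm38. Fn1, the fibronectin gene, stood at 36.0 ± 34.5 against 2044 ± 1619.9 CPM, and Vim, the mesenchymal intermediate filament gene, at 185 ± 94.9 against 1377 ± 957 CPM in the same cells, both short of the threshold (adjusted p = 0.0947 and 0.101 in edgeR). Mki67, a marker of dividing cells, stood at 40.3 ± 19.3 against 12.5 ± 3.69 CPM in whole tumours (log2 fold change 1.64 ± 0.34, adjusted p = 0.0665 in edgeR). In whole tumours the smallest p values belonged to the Notch modifier gene Lfng (-2.45 ± 0.36), Cd74 (-2.96 ± 0.44), Aldoart2 (3.30 ± 0.51), Tgfbi (-1.90 ± 0.30) and the interleukin 7 receptor gene Il7r (-2.67 ± 0.42), each with an adjusted p of 0.0612 in edgeR.

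In whole tumours all 28 G2M genes of cell division lay higher in solid nodular tumours (median 1.26, camera adjusted p = 4.64e-15 preset and 0.149 estimated), and 17 passed when adjusted over the list alone but 0 over all genes. The spindle gene Tpx2 lay at 1.68 ± 0.41 and the cyclin gene Ccnb2 at 1.65 ± 0.41. MHC class II genes lay lower in 10 of 10 cases (median -2.05, camera adjusted p = 4.52e-09 preset and 0.250 estimated), 8 over the list alone. H2-Ab1 lay at -2.40 ± 0.53 and H2-DMa at -1.93 ± 0.43. Macrophage markers lay lower in 12 of 12 cases (median -0.90, camera adjusted p = 0.00200 preset and 0.412 estimated). Interferon genes lay lower in 29 of 29 cases (median -1.51, camera adjusted p = 1.39e-07 preset and 0.362 estimated), 10 over the list alone. Gbp2 lay at -1.81 ± 0.43 and Oasl2 at -1.57 ± 0.41. The antiviral gene Bst2 had 3 UMIs in solid nodular and 178 in metaplastic tumours, a ratio of 0.0464 (95% counting interval 0.00948 to 0.138). T or NK-like cells made up 1.61 ± 1.20% against 8.09 ± 5.02% of cells and macrophage-like cells 9.86 ± 1.56% against 16.8 ± 5.89% (exact permutation p = 0.0667 and 0.0917, adjusted p = 0.367 for both). Genes of the epithelial-mesenchymal transition lay lower in 24 of 24 cases (median -1.30, camera adjusted p = 7.31e-07 preset and 0.362 estimated), 3 over the list alone. S100a4 lay at -2.43 ± 0.69 and Twist2 at -2.64 ± 0.76, and the median was -1.95 without multiparous tumour 4. Fibroblast markers lay as low in the same tumours, in 12 of 12 cases (median -1.35, camera adjusted p = 3.52e-04 preset and 0.412 estimated), and so did 24 of 26 collagen and matrix genes (median -1.24, camera adjusted p = 1.36e-04 preset and 0.534 estimated), with medians of -0.84 and -0.72 without d16 tumour 1. Fibroblast-like cells made up 2.81 ± 2.54% against 4.96 ± 5.60% of cells. Senescence and p53 target genes lay lower in 15 of 16 cases (median -0.996, camera adjusted p = 7.27e-06 preset and 0.298 estimated), 8 over the list alone. The cell cycle inhibitor gene Cdkn2a lay at -2.84 ± 0.79 (on chromosome 4, whose genes had a median of -0.56), Trp53inp1 at -1.62 ± 0.45 and the stress cytokine gene Gdf15 at -1.37 ± 0.38.

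In epithelial-like cells the G2M genes lay higher in 24 of 25 cases (median 1.23, camera adjusted p = 9.13e-11 preset and 0.287 estimated), 6 over the list alone. Cdk1 lay at 1.83 ± 0.56, Tpx2 at 1.84 ± 0.49 and Mki67 at 1.53 ± 0.44, and the median was 0.76 without d16 tumour 1. Genes of the epithelial-mesenchymal transition lay lower in 19 of 19 cases (median -3.70, camera adjusted p = 2.12e-08 preset and 0.287 estimated), 15 over the list alone. Fn1 lay at -5.34 ± 1.13, Vim at -2.77 ± 0.66 and Lgals1 at -4.39 ± 1.10. Fibroblast markers lay lower there in 7 of 8 cases (median -1.38, camera adjusted p = 0.164 preset and 0.640 estimated). Senescence and p53 targets lay lower in 15 of 16 cases (median -1.78, camera adjusted p = 8.31e-07 preset and 0.287 estimated), 11 over the list alone. Phlda3 lay at -3.86 ± 0.84, Gdf15 at -3.09 ± 0.78 and the pro-apoptotic gene Bax at -1.69 ± 0.44. Basal-myoepithelial genes lay lower in 14 of 16 cases (median -3.12, camera adjusted p = 2.60e-06 preset and 0.287 estimated), 11 over the list alone. The laminin gene Lamb3 lay at -4.37 ± 1.09 and Lama3 at -6.63 ± 1.76. The hemidesmosome gene Col17a1 had 0 UMIs in solid nodular and 1427 in metaplastic epithelial-like cells, at least 226-fold lower against a floor of 3 counts over the group and 14.0-fold without multiparous tumour 2. Hormone sensing genes lay lower in 13 of 14 cases (median -3.18, camera adjusted p = 1.73e-05 preset and 0.287 estimated), 9 over the list alone. Foxa1 lay at -4.31 ± 0.86, Ly6a at -4.92 ± 0.97 and Areg at -3.17 ± 0.72. Over all genes 0 members of these 6 lists passed. As for Lgals9, multiparous tumour 4 shows no lower level for genes with a metaplastic mean under 204 CPM, such as Foxa1. Pgr had 2 UMIs against 99, a ratio of 0.0425 (95% counting interval 0.00508 to 0.158). Next in the ranking, at an adjusted p of 0.0744 in edgeR, came Tuba1a (-2.34 ± 0.39), the acute phase gene Hp (-5.73 ± 1.02), the heparan sulfate proteoglycan gene Gpc1 (-3.31 ± 0.59), the p53 target Sfn (-3.31 ± 0.59) and Crip1 (-2.96 ± 0.52). Luminal keratin genes were at -1.46 ± 0.45 for Krt8 and -1.34 ± 0.37 for Krt18, and the cadherin gene Cdh1 at -1.01 ± 0.37.

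**Figure D3:**
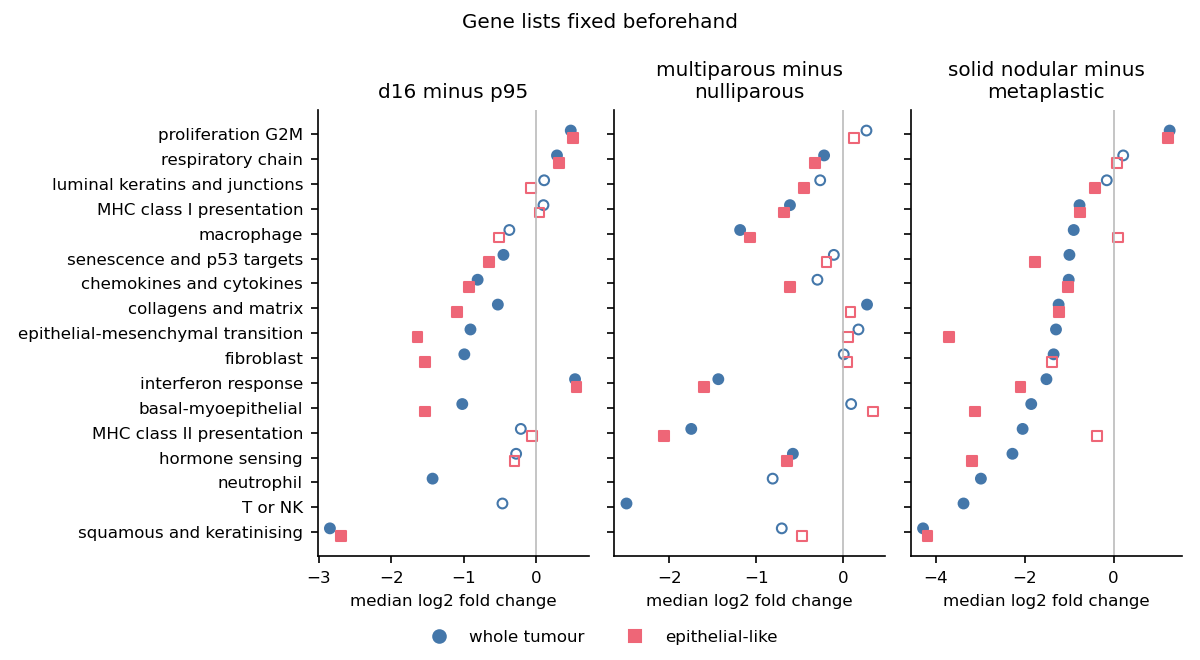
Median log2 fold change of 17 gene lists in each comparison, for whole tumours (circles) and epithelial-like cells (squares). Filled symbols mark lists with a camera adjusted p under 0.05 at a preset correlation of 0.01, and 0 lists passed with an estimated correlation in any of the 6 fits.

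The edgeR test of solid nodular against metaplastic tumours passed 0 of 11394 genes in whole tumours (2229 at an unadjusted p under 0.05, 567 by DESeq2, 21 by limma voom without and 0 with the block) and 1 of 9483 genes in epithelial-like cells (1678 unadjusted, 225 by DESeq2, 9 by limma voom without and 0 with the block). Groups did not overlap for 7.14% of genes in whole tumours and 6.04% in epithelial-like cells, where chance gives 1.67%. The fry test, which asks whether a list's genes move on balance 1 way, passed 6 lists in whole tumours (2 higher, 4 lower) and 0 in the other 5 fits. Epithelial-like cells made up 52.9 ± 43.0% against 47.5 ± 16.3% of kept cells (difference 5.41 points, two-sided exact permutation p = 0.758, smallest p allowed 0.00833, adjusted p = 0.758). That difference was -11.3 points without d16 tumour 1, -2.17 without multiparous tumour 2 and -1.08 in the date-like layout, and with cluster 15 counted in, a choice made after seeing the data, the shares were 75.0 ± 9.79% against 47.5 ± 16.4% (two-sided exact permutation p = 0.0417). Of the 3 solid nodular tumours, d16 tumour 1 was shallow and multiparous tumour 4 gave 15 epithelial-like cells. No gene passed in epithelial-like cells without d16 tumour 1, multiparous tumour 2 or multiparous tumour 4, while 554 passed without d16 tumour 2, 19 without p95 tumour 4 and 4 without p95 tumour 1. In whole tumours 324 genes passed without d16 tumour 2 and 19 without p95 tumour 4, and with file layout as a covariate the counts were 882 in whole tumours and 388 in epithelial-like cells. Within the date-like layout they were 371 and 50, within the intact layout 8 and 0, and with parity as a covariate 0 and 0 (2194 and 1346 unadjusted), where the contrast rests on d16 tumour 1.

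Macrophage-like cells had enough cells in each group for all 3 comparisons, and fibroblast-like cells for parity alone. In macrophage-like cells Gm6548, the pseudogene that led in whole tumours, rose in multiparous tumours to 124 ± 42.2 from 8.33 ± 9.26 CPM (log2 fold change 3.16 ± 0.49, edgeR adjusted p = 0.00829, n = 4 and 8). Scd2, a fatty acid desaturase gene, rose in macrophage-like cells of solid nodular tumours to 173 ± 21.8 from 30.9 ± 17.3 CPM (log2 fold change 2.50 ± 0.42, edgeR adjusted p = 0.0335, n = 3 and 7). Each was the only gene to pass in its fit, of 3274 and 4125 tested, where DESeq2 passed 6 and 21. Between d16 and p95 tumours 0 of 3870 genes passed edgeR in macrophage-like cells (96 at an unadjusted p under 0.05, 0 by DESeq2). In fibroblast-like cells 0 of 1909 genes passed edgeR between 3 multiparous and 5 nulliparous tumours (228 unadjusted, 15 by DESeq2). The count for parity in macrophage-like cells was 0 without multiparous tumour 4, 2 without multiparous tumour 1, 3 without multiparous tumour 2 and 5 with file layout as a covariate. For phenotype it was 0 without p95 tumour 1, 2 or 4, d16 tumour 3 or multiparous tumour 2, 2 without d16 tumour 1 or multiparous tumour 4 and 6 without d16 tumour 2, 17 with file layout as a covariate, and for genotype 1 gene passed without p95 tumour 2 or d16 tumour 3.

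A panel of 18 receptor, lineage and division genes was set before the data were examined, and no gene of it passed in a fit. Log2 fold changes with SE follow, first in whole tumours and then in epithelial-like cells, and a gene short of the count filter is given as untested. Erbb4 was untested throughout. For d16 against p95 they were Erbb2 (0.11 ± 0.47, -0.21 ± 0.43), Egfr (-0.57 ± 0.45, -0.32 ± 0.36), Erbb3 (0.49 ± 1.06, untested), Epcam (0.61 ± 0.48, 0.22 ± 0.40), Cdh1 (-0.37 ± 0.33, -0.50 ± 0.42) and Krt8 (-0.52 ± 0.45, -0.66 ± 0.55). Next came Krt18 (-0.25 ± 0.41, -0.43 ± 0.45), Krt5 (-3.73 ± 1.88, -3.43 ± 1.84), Krt14 (-3.55 ± 1.72, -3.27 ± 1.71), Vim (-0.75 ± 0.60, -1.07 ± 0.69), Esr1 (-0.24 ± 0.49, -0.11 ± 0.70) and Pgr (1.21 ± 0.67, 1.18 ± 0.89) in that comparison. Its last values were Mki67 (0.88 ± 0.62, 0.57 ± 0.60), Csn3 (0.58 ± 0.87, 0.18 ± 0.81), Wap (0.41 ± 1.20, 0.14 ± 1.23), Ptprc (-0.46 ± 0.46, 0.82 ± 1.31) and Col1a1 (-0.97 ± 1.16, -1.30 ± 1.02). For multiparous against nulliparous tumours they were Erbb2 (0.075 ± 0.33, -0.23 ± 0.34), Egfr (-0.14 ± 0.38, -0.078 ± 0.33), Erbb3 (untested, untested), Epcam (-0.15 ± 0.46, -0.41 ± 0.37), Cdh1 (-0.073 ± 0.24, -0.45 ± 0.35) and Krt8 (-0.044 ± 0.37, -0.29 ± 0.47). Also measured there were Krt18 (-0.54 ± 0.32, -0.69 ± 0.38), Krt5 (-0.47 ± 1.66, -0.25 ± 1.54), Krt14 (-0.31 ± 1.49, -0.26 ± 1.43), Vim (0.13 ± 0.50, 0.014 ± 0.75), Esr1 (-0.53 ± 0.50, -0.64 ± 0.57) and Pgr (-2.44 ± 0.74, -2.49 ± 0.98). The remaining parity values were Mki67 (0.34 ± 0.51, 0.24 ± 0.52), Csn3 (0.21 ± 0.98, 0.20 ± 0.77), Wap (-1.07 ± 1.29, -1.30 ± 1.27), Ptprc (-1.06 ± 0.36, untested) and Col1a1 (-0.25 ± 0.90, -0.16 ± 0.82). For solid nodular against metaplastic tumours they were Erbb2 (0.066 ± 0.40, -0.44 ± 0.42), Egfr (-0.83 ± 0.42, -0.38 ± 0.41), Erbb3 (0.34 ± 0.91, untested), Epcam (0.80 ± 0.39, 0.27 ± 0.37), Cdh1 (-0.24 ± 0.28, -1.01 ± 0.37) and Krt8 (-0.84 ± 0.37, -1.46 ± 0.45). Of the next genes, values were Krt18 (-0.86 ± 0.34, -1.34 ± 0.37), Krt5 (-7.55 ± 2.37, -5.62 ± 2.55), Krt14 (-5.68 ± 1.83, -6.41 ± 1.89), Vim (-1.06 ± 0.53, -2.77 ± 0.66), Esr1 (-0.32 ± 0.61, -0.32 ± 0.68) and Pgr (-3.37 ± 0.98, the ratio above). The panel ended with Mki67 (1.64 ± 0.34, 1.53 ± 0.44), Csn3 (1.36 ± 0.94, 1.05 ± 0.69), Wap (-0.65 ± 1.26, -0.84 ± 1.15), Ptprc (-1.04 ± 0.46, 1.58 ± 1.21) and Col1a1 (-1.90 ± 1.04, -1.53 ± 1.10).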

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

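The test used here was fixed before the data were examined, and it ran on shares of cells, total UMIs and the genes named in the text, some of them named for their result. Each value below comes from the gap between the highest or lowest tumour and its nearest neighbour, relative to the range of its group, against Dixon's 95% critical value. Over 143 measures, 571 groups of 4 to 8 tumours were tested and 119 values were set apart. Chance sets a tumour apart in about 1 in 20 groups, and the same tumour counts again in each group it belongs to. Values are CPM without TMM factors, unless given in percent of kept cells. No explanation was weighed for them.

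p95 tumour 1 lay far from the other metaplastic tumours for Cd83 (429), Gdf15 (114) and Tpx2 (0) in the whole tumour. Against the other p95 tumours, p95 tumour 1 stood apart for Gjb1 (9.53) and Pglyrp1 (47.7) in the whole tumour and for Brpf1 (124), Gjb1 (15.4), Mtmr14 (77.2) and Pglyrp1 (77.2) in epithelial-like cells. The value of p95 tumour 1 was set apart from the other nulliparous tumours for H2-DMb1 (257) in the whole tumour. Far from the remaining nulliparous or metaplastic tumours lay p95 tumour 1, for Isg15 (143) and Trp53inp1 (162) in the whole tumour. Set against the other p95, nulliparous or metaplastic tumours, p95 tumour 1 lay outside their range for Ctss (216) and Rasd1 (61.8) in epithelial-like cells. p95 tumour 1 lay far from the other p95 or metaplastic tumours for Rsad2 (77.2) in epithelial-like cells. Against the other nulliparous or metaplastic tumours, p95 tumour 2 stood apart for Cd3d (77.4) and Cd3e (64.3) in the whole tumour. The value of p95 tumour 2 was set apart from the other p95, nulliparous or metaplastic tumours for Krt8 (3011) in the whole tumour. Far from the remaining p95, nulliparous or metaplastic tumours lay p95 tumour 3, for Cdkn2a (77.6), Krt14 (6803), Krt16 (1465), Krt5 (3776), Krt6b (439) and Krtdap (327) in the whole tumour and for Krt6b (716), Krtdap (534) and Sbsn (416) in epithelial-like cells. Set against the other nulliparous or metaplastic tumours, p95 tumour 3 lay outside their range for Rps19-ps3 (47.2) in the whole tumour and for Krt14 (11080) and S100a4 (305) in epithelial-like cells. p95 tumour 3 lay far from the other nulliparous tumours for Rps19-ps3 (60.03) in epithelial-like cells. Against the other nulliparous or metaplastic tumours, p95 tumour 4 stood apart for endothelial-like cells (4.07%) and for Cxcl12 (353) and Egfr (144) in the whole tumour. The value of p95 tumour 4 was set apart from the other p95, nulliparous or metaplastic tumours for fibroblast-like cells (17.1%) and pericyte-like cells (5.78%) and for Ccl2 (251) in epithelial-like cells. Far from the remaining nulliparous or metaplastic tumours lay p95 tumour 5, for Ccl9 (341) in the whole tumour and for Col6a2 (47.6) in epithelial-like cells. Set against the other nulliparous tumours, d16 tumour 1 lay outside their range for Aldoart2 (18), Ccnb2 (112), Mfsd7c (85.5), Mki67 (72), Mtmr14 (248) and Tpx2 (67.5) in the whole tumour and for Cdk1 (225), Mki67 (61.4) and Tpx2 (66.5) in epithelial-like cells. d16 tumour 2 lay far from the other metaplastic tumours for Gjb1 (40.3), Gpx2 (378) and Pglyrp1 (183) in the whole tumour and for Gjb1 (54.1), Gpx2 (512), Ndufs6 (302) and Pglyrp1 (240.4) in epithelial-like cells. Against the other nulliparous or metaplastic tumours, d16 tumour 2 stood apart for Ifi27l2a (389) in epithelial-like cells. The value of d16 tumour 3 was set apart from the other nulliparous or metaplastic tumours for Erbb4 (0.228) in the whole tumour. Far from the remaining nulliparous tumours lay d16 tumour 3, for Pgr (18.0) in the whole tumour. Set against the other metaplastic tumours, d16 tumour 3 lay outside their range for Brpf1 (308) in epithelial-like cells. Multiparous tumour 1 lay far from the other multiparous tumours for Krt6b (83.1), Lfng (14.8), Mmp9 (1168) and Twist2 (129.8) in the whole tumour and for Krt6b (177) in epithelial-like cells. Against the other multiparous tumours, multiparous tumour 2 stood apart for Csn3 (28774), Gpx2 (279.6), Mfsd7c (26.7) and Wap (99.5) in the whole tumour and for Gpx2 (349) in epithelial-like cells. The value of multiparous tumour 4 was set apart from the other multiparous tumours for Gjb1 (318) and Rps19-ps3 (226) in the whole tumour and for 1600029O15Rik (136), Krtdap (204) and Tpx2 (136) in epithelial-like cells. The Erbb4 value and both Gjb1 values of p95 tumour 1 rest on 1 UMI each. In that tumour both Pglyrp1 values and the epithelial-like Mtmr14 and Rsad2 values rest on 5 UMIs, the Rasd1 value on 4 and the epithelial-like Brpf1 value on 8, where 3 counts would be 46.3 CPM in epithelial-like cells. Aldoart2 in d16 tumour 1 rests on 4 UMIs. Tpx2 had 0 UMIs in the whole of p95 tumour 1, where 3 counts would be 28.6 CPM, above the 7.42 to 12.4 CPM of the other metaplastic tumours, so that 0 does not show a lower level. In multiparous tumour 4, 1600029O15Rik and Tpx2 rest on 2 UMIs and Krtdap on 3, and the epithelial-like values of multiparous tumour 4 on 15 cells.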

How the results depend on the processing

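Settings tried after seeing the data were the file layout as a covariate, each layout alone, the fits without the 2 shallowest tumours (p95 tumour 1 and d16 tumour 1), limma voom without a block, cluster 15 counted as epithelial-like and cells thinned to 400 UMIs. Counts of passing genes kept within 1.5 times their reported value with RLE normalisation and with predicted doublets removed in all 6 fits of whole tumours and epithelial-like cells. For d16 against p95, DESeq2 passed 3 genes in whole tumours and 2 in epithelial-like cells, and without the low-count filter or under limma voom with the title number as a block 1 gene passed in epithelial-like cells. Leaving out each tumour gave 0 to 2 genes in whole tumours. For parity in whole tumours, DESeq2 passed 157 genes, limma voom 15 without and 3 with the block, phenotype as a covariate 0, file layout as a covariate 4, the date-like layout 4 and the fit without the 2 shallowest tumours 4, and leaving out each tumour gave 3 to 20. With phenotype as a covariate the contrast rests on d16 tumour 1 against multiparous tumours 2 and 4, and with parity as a covariate the phenotype contrast rests on d16 tumour 1 against the 7 metaplastic tumours, since no multiparous tumour is metaplastic. Of the 9 reported genes, 4 were among those passing with file layout as a covariate and 3 among those passing with the block. In epithelial-like cells DESeq2 passed 5 genes and leaving out each tumour gave 0 to 1. For phenotype in whole tumours, 33 genes passed without the low-count filter, 567 under DESeq2, 21 under limma voom without and 0 with the block, 882 with file layout as a covariate, 371 within the date-like layout, and 0 to 324 on leaving out each tumour. In epithelial-like cells, 13 passed without the filter, 225 under DESeq2, 9 under limma voom without and 0 with the block, 12 with 500 or more detected genes per cell, 388 with file layout as a covariate, 50 within the date-like layout, 24 with cluster 15 and 9 with thinned cells. There 0 passed with parity as a covariate or without the 2 shallowest tumours, and leaving out each tumour gave 0 to 554. Without the low-count filter 16, 55 and 64 genes passed in macrophage-like cells for genotype, parity and phenotype, and 53 in fibroblast-like cells, and with file layout as a covariate 0, 5 and 17 in macrophage-like cells. The camera calls of all 6 fits ended with an estimated correlation, which left 0 lists, while RLE normalisation and file layout as a covariate kept their counts within 1.5 times. Of the passing genes, Gm12657 passed in 22 of 23 settings (adjusted p 1.94e-08 to 0.360), Gm6548 in 15 of 23 (highest 0.359), Rps19-ps3 in 7 of 23 (highest 0.360), Il21r in 9 of 23 (highest 0.432), Il10 in 8 of 23 (highest 0.421), Il10ra in 6 of 23 (highest 0.360) and Lgals9 in 18 of 25 (adjusted p 8.71e-09 to 0.398), with fold changes of 1 sign throughout. The share of epithelial-like cells in d16 less p95 tumours was -8.62 points within the date-like layout and 5.28 to 33.0 on leaving out each tumour. For multiparous less nulliparous tumours it was 4.20 points within the date-like layout, 5.72 with cluster 15 and -19.7 to 1.54 on leaving out each tumour. For solid nodular less metaplastic tumours it was -1.08 points within the date-like layout, -8.07 without the 2 shallowest tumours, 27.5 with cluster 15 and -11.3 to 29.7 on leaving out each tumour. The title number is shared by p95 tumour 2 and d16 tumour 2 and by d16 tumour 3 and p95 tumour 4, and of the 5 other pairs of a d16 and a p95 tumour of 1 layout 3 correlated more highly than those that share it and 2 less. The cause was not tested for any of these shifts. Depth limits the fits, since p95 tumour 1 gave 64781 UMIs in epithelial-like cells and multiparous tumour 4 14725.

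Genes named in the text kept their sign in most settings, and the values that turned sign follow, all for genes that passed in none of the reported fits. Within the date-like layout, the log2 fold change turned sign for Cdh1 (0.023), Erbb2 (-0.20), Esr1 (0.53), Krt18 (0.23), Krt8 (0.16), Mki67 (-0.049) and Ptprc (0.40) between d16 and p95 whole tumours, for Cdh1 (0.25), Esr1 (1.56), Krt18 (0.44), Krt8 (0.33) and Mki67 (-0.013) between d16 and p95 epithelial-like cells, for Cdh1 (0.035), Epcam (0.66), Krt8 (0.073) and Vim (-0.43) between multiparous and nulliparous whole tumours, for Epcam (0.033), Erbb2 (0.20) and Vim (-0.68) between multiparous and nulliparous epithelial-like cells, for Cdh1 (0.16) between solid nodular and metaplastic whole tumours and for Erbb2 (0.19) and Esr1 (0.21) between solid nodular and metaplastic epithelial-like cells. In metaplastic tumours alone, the log2 fold change turned sign for Csn3 (-0.085) and Mki67 (-0.070) between d16 and p95 whole tumours and for Csn3 (-0.20), Esr1 (0.041), Mki67 (-0.15) and Ptprc (-0.90) between d16 and p95 epithelial-like cells. With all 12 tumours in 1 fit, the log2 fold change turned sign for Csn3 (-0.091) and Mki67 (-0.091) between d16 and p95 whole tumours and for Csn3 (-0.17), Esr1 (0.059), Mki67 (-0.13) and Ptprc (-0.87) between d16 and p95 epithelial-like cells. With file layout as a covariate, the log2 fold change turned sign for Erbb2 (-0.23) and Erbb3 (-0.55) between d16 and p95 whole tumours, for Ptprc (-0.43) between d16 and p95 epithelial-like cells, for Cdh1 (0.029), Epcam (0.65), Krt8 (0.070) and Vim (-0.43) between multiparous and nulliparous whole tumours and for Epcam (0.032), Erbb2 (0.20) and Vim (-0.66) between multiparous and nulliparous epithelial-like cells. Within the intact layout, the log2 fold change turned sign for Erbb2 (-0.31) between d16 and p95 whole tumours, for Csn3 (-0.26), Epcam (-0.084) and Ptprc (-0.085) between d16 and p95 epithelial-like cells and for Erbb2 (-0.86) between solid nodular and metaplastic whole tumours. Under limma voom with the title number as a block, the log2 fold change turned sign for Erbb3 (-0.44) between d16 and p95 whole tumours, for Esr1 (0.29) and Ptprc (-0.25) between d16 and p95 epithelial-like cells, for Cdh1 (0.023), Col1a1 (0.67), Csn3 (-0.82) and Krt8 (0.091) between multiparous and nulliparous whole tumours, for Col1a1 (0.57), Csn3 (-0.018), Egfr (0.0098), Krt14 (0.53) and Vim (-0.44) between multiparous and nulliparous epithelial-like cells, for Wap (0.56) between solid nodular and metaplastic whole tumours and for Esr1 (0.30) and Wap (1.03) between solid nodular and metaplastic epithelial-like cells. Under limma voom without a block, the log2 fold change turned sign for Erbb3 (-0.26) and Esr1 (0.011) between d16 and p95 whole tumours, for Esr1 (0.35) and Ptprc (-0.082) between d16 and p95 epithelial-like cells, for Col1a1 (0.58), Csn3 (-0.95), Krt14 (0.020) and Krt8 (0.017) between multiparous and nulliparous whole tumours, for Col1a1 (0.59), Csn3 (-0.16), Krt14 (0.51), Krt5 (0.0052) and Vim (-0.42) between multiparous and nulliparous epithelial-like cells, for Wap (0.089) between solid nodular and metaplastic whole tumours and for Esr1 (0.23) and Wap (0.59) between solid nodular and metaplastic epithelial-like cells. Without the 2 shallowest tumours, the log2 fold change turned sign for Mki67 (-0.026) between d16 and p95 whole tumours, for Csn3 (-0.026), Erbb2 (0.11), Esr1 (0.093) and Mki67 (-0.062) between d16 and p95 epithelial-like cells, for Epcam (0.12) and Vim (-0.15) between multiparous and nulliparous whole tumours and for Vim (-0.28) between multiparous and nulliparous epithelial-like cells. With 500 or more detected genes per cell, the log2 fold change turned sign for Ptprc (-0.11) between d16 and p95 epithelial-like cells and for Vim (-0.052) between multiparous and nulliparous epithelial-like cells. With phenotype as a covariate, the log2 fold change turned sign for Cd3e (4.70), Cdh1 (0.80), Col1a1 (5.50), Csn3 (-0.069), Egfr (0.37), Irf7 (0.051), Krt14 (9.29), Krt5 (6.23), Krt8 (0.96), Mki67 (-1.04), Pgr (3.69) and Wap (3.79) between multiparous and nulliparous whole tumours and for Cdh1 (0.64), Cldn4 (1.44), Cldn7 (0.74), Col1a1 (1.11), Erbb2 (0.44), Esr1 (0.80), Krt14 (8.81), Krt18 (0.15), Krt19 (3.98), Krt5 (9.35), Krt8 (1.11), Mki67 (-0.67), Pgr (2.73), Vim (-0.59) and Wap (4.51) between multiparous and nulliparous epithelial-like cells. With cluster 15 counted as epithelial-like, the log2 fold change turned sign for Col1a1 (0.29) and Csn3 (-0.040) between multiparous and nulliparous epithelial-like cells. With cells thinned to 400 UMIs, the log2 fold change turned sign for Erbb2 (0.19) between multiparous and nulliparous epithelial-like cells and for Erbb2 (0.0048) between solid nodular and metaplastic epithelial-like cells. Without predicted doublets, the log2 fold change turned sign for Vim (-0.014) between multiparous and nulliparous epithelial-like cells. With parity as a covariate, the log2 fold change turned sign for Erbb2 (-0.25) between solid nodular and metaplastic whole tumours. Whole tumours, compared between d16 and p95, gave log2 fold changes of -0.085 to 0.97 for Csn3, -0.47 to 0.46 for Erbb2, -1.30 to 1.31 for Erbb3, -0.69 to 0.066 for Esr1, -0.46 to 0.10 for Krt18, -0.070 to 1.38 for Mki67 and -0.21 to 1.83 for Wap on leaving out each tumour. Epithelial-like cells, compared between d16 and p95, gave log2 fold changes of -3.90 to 0.16 for Col1a1, -0.20 to 0.44 for Csn3, -0.96 to 0.69 for Esr1, -0.15 to 1.03 for Mki67, -0.90 to 1.65 for Ptprc and -0.27 to 1.72 for Wap on leaving out each tumour. Whole tumours, compared between multiparous and nulliparous, gave log2 fold changes of -0.15 to 0.065 for Cdh1, -0.77 to 0.049 for Col1a1, -2.56 to 0.59 for Csn3, -0.33 to 0.17 for Egfr, -0.62 to 0.079 for Epcam, -0.029 to 0.24 for Erbb2, -0.99 to 1.25 for Krt14, -1.43 to 1.36 for Krt5, -0.30 to 0.19 for Krt8, -0.14 to 0.73 for Mki67 and -0.088 to 0.38 for Vim on leaving out each tumour. Epithelial-like cells, compared between multiparous and nulliparous, gave log2 fold changes of -0.68 to 0.85 for Col1a1, -1.24 to 0.55 for Csn3, -0.19 to 0.13 for Egfr, -1.11 to 1.01 for Krt14, -1.23 to 1.27 for Krt5, -0.54 to 0.55 for Mki67 and -0.66 to 0.37 for Vim on leaving out each tumour. Whole tumours, compared between solid nodular and metaplastic, gave log2 fold changes of -0.056 to 0.27 for Erbb2, -0.51 to 0.74 for Erbb3 and -1.82 to 0.26 for Esr1 on leaving out each tumour. Epithelial-like cells, compared between solid nodular and metaplastic, gave log2 fold changes of -1.19 to 0.048 for Esr1 and -1.22 to 2.61 for Ptprc on leaving out each tumour. The cause of these turns was not tested.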

Other observations

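The tests of file layout for the genes of chromosome 6 and for the pseudogenes, and every count of other splits, were chosen after the result was seen. The mixed tumours, multiparous 1 and 3, belong to neither side of the phenotype comparison, and their values are given here as CPM without TMM factors. In epithelial-like cells Lgals9 stood at 136 and 116 CPM (means 6.65 solid nodular, 167 metaplastic), Fn1 at 3399 and 6779 CPM (means 33.9 solid nodular, 1864 metaplastic) and Vim at 1826 and 2563 CPM (means 199 solid nodular, 1251 metaplastic). Areg, the EGF receptor ligand gene, stood at 817 and 920.0 CPM (means 78.3 solid nodular, 743 metaplastic). In whole tumours Mki67 stood at 10.8 and 9.72 CPM (means 43.7 solid nodular, 12.3 metaplastic), Krt5 at 1178 and 737 CPM (means 4.09 solid nodular, 717 metaplastic) and Krt14 at 2215 and 1887 CPM (means 27.1 solid nodular, 1398 metaplastic). Cd74 stood at 243 and 201 CPM (means 166 solid nodular, 1174 metaplastic) and the casein gene Csn3 at 1964 and 1212 CPM (means 15895 solid nodular, 5898 metaplastic).

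Among other gene groups, hypoxia and glycolysis genes lay higher in multiparous whole tumours, in 23 of 26 cases (median 0.34, camera adjusted p = 3.44e-05 preset and 0.294 estimated), with a median of 0.53 without p95 tumour 3. Fatty acid and sterol synthesis genes lay higher in solid nodular whole tumours, in 22 of 25 cases (median 0.38, camera adjusted p = 2.99e-04 preset and 0.149 estimated), as did S phase genes in 23 of 24 cases (median 0.71, camera adjusted p = 1.74e-05 preset and 0.362 estimated). Without multiparous tumour 4 those 2 medians were 0.10 and 0.24. Hormone sensing genes lay lower there in 15 of 16 cases (median -2.28, camera adjusted p = 1.75e-05 preset and 0.136 estimated).

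Splits of the same tumours into groups of the same sizes, the real one included, were counted, all 56 for genotype and for parity in fibroblast-like cells, and 100 otherwise. The 0 genes of edgeR for genotype in the 3 classes of cells, for parity in epithelial-like and fibroblast-like cells and for phenotype in whole tumours are met by every split by construction (56 of 56 and 100 of 100), so these counts say nothing about chance. The highest other counts were 912 genes in whole tumours and 596 in epithelial-like cells for genotype, both with p95 tumour 1 and d16 tumours 1 and 2 against the rest, all 3 of the intact layout. Within the layouts edgeR passed 0 genes in both classes of cells (524 and 184 in whole tumours at an unadjusted p under 0.05). For parity, 852 genes passed in epithelial-like cells under another split, and 227 for phenotype in whole tumours with d16 tumours 1 and 2 and multiparous tumour 2 against the rest. For the 9 parity genes in whole tumours chance was argued against only weakly (3 of 100 splits gave as many, the real one among them). A split of d16 tumours 1 and 2, p95 tumour 2 and multiparous tumour 2, of which 3 have the intact layout, gave 639. Lgals9, the 1 gene of phenotype in epithelial-like cells, was matched by 13 of 100 splits with up to 800 genes, so chance could not be excluded. Counts this far above the real ones may come from a structure of the samples other than the compared groups, which was not tested. For the 16 lists of genotype in epithelial-like cells 1 of 56 splits gave as many (highest other 15). For the 21 of phenotype in whole tumours 3 of 100 did (highest other 21). At the preset correlation chance was argued against only weakly in both, since other splits had medians of 10 to 14 over the 6 fits. Margins were 1 and 0 lists, and 0 passed in either with an estimated correlation. Chance could not be excluded for the 17 lists of genotype in whole tumours (10 of 56, highest other 18), the 14 and 11 lists of parity (46 of 100 and 45 of 100, highest other 20 and 17) or the 15 lists of phenotype in epithelial-like cells (10 of 100, highest other 18). Nor could it in macrophage-like cells for the 1 and 1 genes of parity and phenotype (9 of 100 and 21 of 100, highest other 10 and 35). The highest other counts were 20 for genotype in macrophage-like and 3 for parity in fibroblast-like cells.

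The next 3 patterns came from an unplanned look at 20 chromosomes, at windows of 11 neighbouring genes and at gene types in the 6 fits of whole tumours and epithelial-like cells, so each is a hypothesis found and tested on the same data.

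In epithelial-like cells of solid nodular against metaplastic tumours, the 563 tested genes of chromosome 4 had a median log2 fold change of -0.74, where the medians of the other chromosomes ran from -0.17 to 0.20. File layout and depth were argued against by the date-like layout alone, where the median was -0.79 and the lowest of the others -0.21, and a difference carried by all cells of a tumour by macrophage-like cells, where the median was -0.084 and the lowest of the others -0.14. With cluster 15 counted in, all 3 solid nodular tumours deviated further below the mean of the tumours (-0.64 in d16 tumour 1, -0.50 and -0.52 in multiparous tumours 2 and 4) than every metaplastic tumour (lowest -0.29, in d16 tumour 2), and the mixed multiparous tumours 1 and 3 stood at 0.14 and 0.25. Growth pattern was not alone in this, since the median was -0.42 in d16 against p95 (-0.084 in the date-like layout) and -0.18 in multiparous against nulliparous tumours (-0.31 in the date-like layout), and d16 tumour 2 stood at -0.58 over 16 genes up to 20 Mb and -0.49, -0.40, -0.29 and -0.51 over 9, 67, 10 and 22 in the next 4 pieces of 20 Mb, in each lower than at least 1 solid nodular tumour. Loss of chromosome 4 in the tumour cells may account for its lower medians, and neither DNA copy number nor the order of loss and growth pattern was measured.

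In d16 against p95 tumours 8 genes from Srgap3 to Tada3, picked for being higher, Mtmr14 and Brpf1 among them, lay beside Gt(ROSA)26Sor on chromosome 6, a locus often used to insert transgenes, with log2 ratios of summed CPM of 1.57 in whole tumours and 1.65 in epithelial-like cells with cluster 15 counted in, while the next tested genes, Rad18 and Arpc4, lay lower (-0.68 and -1.02). Of 10481 windows in whole tumours the one over this locus had the highest median, and of 8740 in epithelial-like cells the second highest. File layout and depth were argued against by such windows, all genes included, in whole tumours of the intact layout alone, where the one over the locus ranked 1 of 7957 (2 d16 against 2 p95 tumours), and without the 2 shallowest tumours (1 of 10782), but not in epithelial-like cells, where it ranked 145 of 6032 in the intact layout and 41 of 8740 with layout as a covariate (median 0.48, from 0.98). Over all tumours a difference carried by every cell of the animals was argued against by the immune classes, where the ratio was 0.32 (-0.041 to 0.52 on leaving out each tumour) under the bound of 0.83 set by an epithelial-like ratio that the picking raises, but the intact layout alone, with 0.67 in immune classes beside 1.17 in epithelial-like cells, did not show it (16 and 12 immune UMIs of these genes in d16 tumour 1 and p95 tumour 1, without which the ratios over the rest were -0.058 and 1.57). Transcription of the transgenes in tumour cells, if they lie there, may account for these genes, but their position was not given in the sources used here and no test addressed it.

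Of the 6 genes that rose in multiparous whole tumours, 5 are processed pseudogenes in the annotation and 1, Rnps1, is protein coding. Among all tested processed pseudogenes 20 of 40 were higher at an unadjusted p under 0.05, against 2.58% of protein coding genes, and in solid nodular tumours, of which 2 of 3 are multiparous, 12 of 37 against 8.11% (0 of 37 with parity as a covariate, a contrast resting on d16 tumour 1). File layout and depth were argued against for the group by the date-like layout alone, where 57.9% of 38 pseudogenes (exact 95% interval 40.8 to 73.7%) and 4.49% of protein coding genes were higher, and for 4 of the 6 genes, which passed there in edgeR over all genes tested, but 0 of the other 2 did, Rps19-ps3 and Rnps1 (2.30 ± 0.54 and 2.66 ± 0.45), for which they stay open. Reads shared with the parent genes and counted differently in the multiparous libraries may account for the rise of the 6 genes, since the log2 ratio of their summed CPM was 3.19 in immune classes, 3.04 in epithelial-like cells with cluster 15 counted in and 3.10 in whole tumours, alike in cells of different origin. A strain difference between the animals would give the same and was not tested, and neither was a step of the processing that all multiparous libraries share.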
